A study of Mus musculus with 2 samples.

How the data were processed

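The data were single-cell RNA-seq counts from tumour-infiltrating lymphocytes of B16 Pten-/- tumours in C57BL/6 mice. B16 is a mouse melanoma line, and in this derivative the tumour suppressor gene Pten is lost. PTENα is a longer protein form of PTEN made from an upstream start codon. Tumour cells carried either a Mock construct or a construct for PTENα, and each group was 1 library. The number of animals behind a library, and any sort or enrichment of the cells, are not given in the sources used here. Libraries were made with the 10x Chromium 3' v3.1 chemistry, per the labels' protocols, so each UMI marks 1 captured transcript, read near its 3' end.

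The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 5.0.0, per the file headers. Seurat 3.2.3 and the genome builds mm10 and GRCm38 are named in the submitters' processing notes, and no step done with Seurat is visible in the matrices, which hold whole numbers. Both matrices list 32285 genes, in the same order. The annotation release behind the counts is not given in the sources used here. There were 78 gene IDs that shared a symbol with another ID, and these were kept apart by ID. Gene coordinates were looked up by gene ID in GENCODE vM21 on GRCm38, and all 90 genes looked up were found.

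The Mock matrix held 5212 barcodes and 14758646 UMIs, and the PTENα matrix held 4319 barcodes and 13100660 UMIs. Barcodes with at least 200 detected genes and at most 10% of UMIs from mitochondrial genes were kept. In Mock 28 barcodes lay under the gene minimum and 193 (3.70%) over the mitochondrial limit. In PTENα the numbers were 8 and 500 (11.6%). Scrublet's automatic threshold, through scanpy, marked only 3 Mock and 2 PTENα barcodes and was not used. Instead the barcodes with the highest Scrublet scores were removed, in number 0.8% per 1000 barcodes of that library, which came to 200 and 116. This left 4798 Mock cells with 13571916 UMIs and 3699 PTENα cells with 11930487 UMIs.

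Counts were scaled to 10000 per cell and log-transformed. Clustering used 2000 variable genes without antigen receptor variable segments, mitochondrial, ribosomal and haemoglobin genes, Xist and Y-linked genes. It then used 30 principal components, 15 neighbours and the Leiden method at resolution 1 with seed 0, with no integration of the libraries. Each cluster was scored against 23 marker sets fixed before the data were examined. A marker's score was the cluster's CPM (UMIs of a gene scaled to the cluster's total, as in all CPM values here) over the highest CPM of any cluster, and it was 0 where no cluster reached 50 CPM. The set with the highest mean score named the cluster if at least 3 of its markers stood at 0.25 or more of that highest CPM and were seen in at least 10% of the cluster's cells. A cluster with a median depth under 0.333 of that of its library and no marker of its own among its 10 leading genes would have stayed unnamed, which befell none. Rules set after the clusters were seen left a cluster with fibroblast markers unnamed where keratin genes were among its 10 leading genes, and a recluster of T cells unnamed where Lyz2 was. A recluster of T cells also stayed unnamed where markers of another subset outnumbered its own among these genes. Leading genes were ranked by fold over the other clusters with 10 CPM added. T cells were reclustered alone in the same way to name subsets, and gates on UMIs of Cd8a, Cd8b1, Cd4, Foxp3, Trdc and Tcrg-C1 gave a second call.

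With 1 library per group no test across samples exists, so no p-value, standard error or number of changed genes is given. Shares carry exact Clopper-Pearson intervals, CPM values carry exact Poisson intervals and ratios carry exact conditional binomial intervals, all at 95% and all covering counting error only. Beside a count of 0 the limit given is the share or level that 3 counts would make, which for shares limits cells with a UMI, not cells that express the gene. Expression was compared as UMIs summed over all kept cells, and over each named class with at least 100 kept cells in each library, which gave 4 classes. A log2 ratio against a count of 0 used a floor of 3 counts. Shares of cells with a UMI were taken after each cell was thinned to 1000 UMIs, and shallower cells were left out.

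The rule for named genes was fixed before the data were examined. A named gene has at least 50 UMIs and 50 CPM in the library where it is higher, and the bound of its ratio nearest to 1 is past 1.5-fold. Ranked by that bound, the first 10 higher and 10 lower genes over all cells, and the first 8 of each in a class, are named. Antigen receptor segments, immunoglobulin constant genes outside B and plasma cells, mitochondrial, ribosomal and haemoglobin genes, Xist, Y-linked genes and unnamed gene models were left out of the ranking. Within a class, genes whose CPM was more than 5 times higher in another class of the same library were left out too, as possible free RNA.

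There were 21 fixed gene lists: cytotoxic effector, inhibitory receptors and exhaustion, naive and memory T, T cell activation and costimulation, Treg effector, interferon-stimulated genes, interferon-gamma response, MHC class I, MHC class II, immunosuppressive myeloid, complement and scavenging macrophage, inflammatory cytokines and chemokines, chemokine receptors and trafficking, NK receptors, hypoxia, glycolysis, oxidative phosphorylation, cell cycle, PI3K-AKT and PTEN pathway, dissociation stress and immediate-early, and apoptosis and p53. They hold 477 different genes, of which 5 (Aldoa, Cd206, Cxcl11, Mx1 and Mx2) matched no unique symbol of the matrices. Of these, Aldoa is the symbol of 2 gene IDs there, and the 4 others were not among the symbols. A list's value is the median log2 ratio, PTENα over Mock, of members with at least 20 UMIs over both libraries. Its percentile is its place among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries. Members at or past 1.5-fold are counted as higher or lower and the others as between.

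The code was tested on simulated data with the real genes and library sizes, with 50 genes changed by each of 4 folds, either up or down. Of genes changed 2-fold, 100% passed the 1.5-fold bound in the right direction over all cells, 96% in monocytes or macrophages, 70% in T cells, 68% in neutrophils and 60% in NK cells. At 3-fold the recovery was 98% or 100% in all 5 sets, and at 4-fold it ran from 96% to 100%. At 1.5-fold, which is the bound itself, it was 2% over all cells, in NK cells and in T cells and 0% in the others. Intervals held the true ratio for 95.5% of genes over all cells, 96.5% in NK cells, 96.5% in T cells, 96.1% in monocytes or macrophages and 95.7% in neutrophils. No unchanged gene passed the bound in any set. Simulated sums were Poisson draws from a profile shared by both libraries, with no variation between cells or libraries beyond counting. The simulation therefore checks the code and does not show how often real libraries pass the bound without a group difference. Of unchanged lists, 6.5% over all cells, 4.5% in NK cells, 5% in T cells, 8% in monocytes or macrophages and 5% in neutrophils lay outside the middle 95% of random lists, and a list with every member changed 1.5-fold reached percentile 100 in each set.

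Alternatives planned before the data were examined were mitochondrial limits of 5% and 20%, a minimum of 500 genes, no doublet removal or double the number removed, Leiden resolutions 0.5 and 2, 15 principal components, each library clustered alone, calls per cell by marker means, gates for T subsets, immune cells as the denominator, thinning to 500 or 2000 UMIs, median-of-ratios scaling, means over cells, thinned classes for single genes, other minimum counts, equal class weights and the main cluster of a class alone for gene lists. Alternatives added after the data were seen were the main cluster alone for single genes, thinned classes for gene lists, T subsets named without the rule on Lyz2, and 3 sets of cells. These were cells without an Xist UMI, cells with a Y-linked UMI and no Xist UMI, and cells outside the B, plasma and Lef1-high T clusters, where Lef1-high means a T cluster at 200 CPM of Lef1 or more. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.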

Results

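Single-cell RNA-seq was used to describe the immune cells taken from B16 melanomas that lack Pten and carried either a Mock construct or a construct for PTENα, the longer form of the PTEN protein. The question set by the design is how the infiltrate of PTENα tumours differs from that of Mock tumours. Each group was 1 library of 10x 3' counts from C57BL/6 mice. The Mock library held 5212 barcodes and 14758646 UMIs, with a median of 1900 UMIs and 786 genes per barcode. The PTENα library held 4319 barcodes and 13100660 UMIs, with a median of 2590 UMIs and 1072 genes. Barcodes over the limit of 10% mitochondrial UMIs made up 3.70% of Mock and 11.6% of PTENα. After filtering and removal of likely doublets 4798 Mock and 3699 PTENα cells remained, with medians of 1900 and 2832 UMIs. With 1 library per group every difference has no replicate check, group, library and batch cannot be told apart, and all intervals are 95% intervals that cover counting error only.

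Clusters were named from fixed markers as B-like, T-like, monocyte- or macrophage-like, neutrophil-like, NK-like, conventional dendritic cell (cDC)-like, plasmacytoid dendritic cell (pDC)-like, CCR7 dendritic cell-like and plasma-cell-like, and the suffix is left out from here on. B cells formed clusters 0 and 2, where the B cell receptor component Cd79a and the IgM Fc receptor Fcmr were among the genes that set them apart, and cluster 7, which was led by Mef2b, Aicda and Mki67. T cells formed clusters 1 and 5, with high Lef1 and Dapl1, and cluster 3, led by Il17a, Tnfrsf4, Cxcr6, Trdc, Pdcd1 and Ctla4. Monocytes or macrophages formed clusters 9 (Il1a, Ccl2, Il6, Ccl24), 10 (Chil3, Mgst1), 11 (C1qa, C1qb, Mrc1, Pf4) and 12 (Hspa1a, Hmox1, Mmp12, Arg1). Neutrophils formed clusters 4 (S100a8, S100a9, Retnlg) and 6 (Cstdc4, Stfa2l1, G0s2), and NK cells formed cluster 8, led by Gzmc, Gzmd, Gzma and Prf1. Calls per cell by marker means put 193 cells of cluster 8 with NK cells and 101 with T cells, and of the monocytes or macrophages they put 1705 cells with the same class, 490 with neutrophils and 54 with T cells. Conventional dendritic cells formed cluster 15, of which such calls put 105 cells with these cells, 106 with monocytes or macrophages and 106 with neutrophils. Cluster 16, with 17 Mock and 31 PTENα cells, expressed Rhox5, Krt8 and Col3a1 and was left unnamed, although its highest marker score was that of fibroblasts. Of the genes looked up for melanocytes, Mitf had 84 and 243 UMIs and Slc24a5 119 and 57 UMIs in Mock and PTENα barcodes. A core set of 5 melanocyte genes had 3 UMIs in all Mock barcodes and 2 in all PTENα barcodes, and 0 of 4641 Mock and 0 of 3101 PTENα cells had an Mlana UMI after thinning, which allows shares of cells with a UMI of up to 0.0646% and 0.0967% and sets no limit on cells that express the gene below detection.

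Pten itself (ENSMUSG00000013663, GRCm38 chromosome 19, 32757497 to 32826160), the lipid phosphatase that opposes PI3K signalling, was detected in the infiltrating cells of both libraries, which come from the host. Over all cells it stood at 153 CPM in Mock (146 to 160) and 132 CPM in PTENα (126 to 139). B cells held 1147 of the 2074 Pten UMIs of Mock, at 198 CPM, and 7 of the 1580 of PTENα. The levels over all cells therefore also follow the class shares, and no order is read from them. In monocytes or macrophages Pten was at 169 CPM (153 to 186) against 144 CPM (136 to 153). Pten intervals of the libraries overlapped in neutrophils (148 and 163 CPM), in NK cells (52.4 and 68.9 CPM) and in T cells (84.0 and 99.2 CPM). A 3' tag of Pten does not separate host Pten from an introduced sequence and checks nothing about the tumour cells.

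Kept cells of the PTENα library were mostly myeloid and those of the Mock library mostly lymphoid. Most Mock lymphoid cells differed from Mock myeloid cells in sex-linked transcripts, as given below. Class shares are therefore not read as differences between the tumours. B cells made up 54.8% of Mock cells (2628 cells, 53.4 to 56.2) and 1.41% of PTENα cells (52 cells, 1.05 to 1.84), which was 39.0-fold lower in PTENα (29.6 to 52.3). T cells were 4.38-fold lower (3.76 to 5.13), at 23.1% (21.9 to 24.3) against 5.27% (4.57 to 6.04). Monocytes or macrophages, the phagocytes of the tumour bed, were 5.92-fold higher in PTENα (5.32 to 6.60), at 8.57% (7.79 to 9.39) against 50.7% (49.1 to 52.3). Neutrophils were 3.04-fold higher (2.70 to 3.43), at 8.36% (7.59 to 9.18) against 25.4% (24 to 26.8). Conventional dendritic cells, which present antigen to T cells, were 8.32-fold higher (6.12 to 11.5), at 1.0% against 8.33%, and NK cells were 2.48-fold higher (1.95 to 3.18), at 2.15% against 5.33%. The log2 ratio of the dendritic share, 3.06, was 2.04 with at most 5% mitochondrial UMIs. With each library clustered alone the log2 ratios of the T and NK shares were −1.18 and 0.58, in place of −2.13 and 1.31. Plasmacytoid dendritic cells were 3.96-fold higher (2.35 to 6.92) and CCR7 dendritic cells 2.24-fold higher (1.29 to 3.98). Plasma cells numbered 40 in Mock and 1 in PTENα, a 30.8-fold lower share (5.23 to 1248). The direction of the neutrophil and NK shares turned in 2 of 3 smaller sets of cells, as given with the Xist and Y-linked transcripts. In those 2 sets the log2 ratio of monocytes or macrophages was 0.61, in place of 2.57. That of conventional dendritic cells was 1.10 and 1.31 there, in place of 3.06. The neutrophil difference also shrank to a log2 ratio of 0.30 with at least 500 genes per barcode. NK shares are not independent of granzyme levels, because granzymes define cluster 8.

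**Figure D1:**
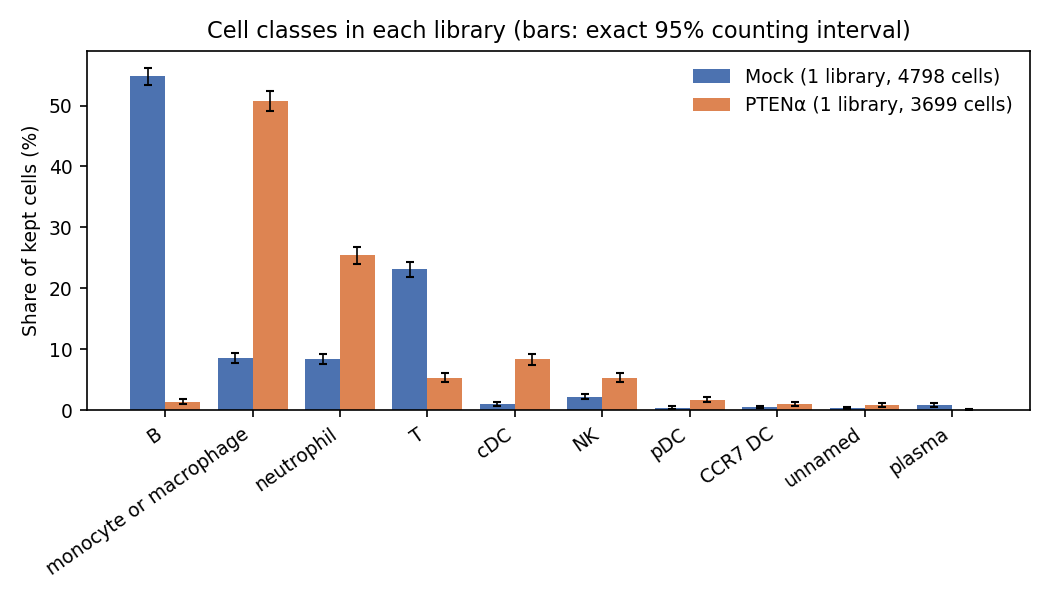
Share of kept cells (percent, vertical axis) in each marker-based class for the Mock (4798 cells) and PTENα (3699 cells) libraries, with bars for the shares and exact 95% binomial intervals as error bars. B cells stood at 54.8% in Mock and 1.41% in PTENα, and monocytes or macrophages at 8.57% and 50.7%.

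The lymphoid excess of the Mock library lay in B cells, plasma cells and T cells with high Lef1 (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356), a transcription factor of naive T cells. T clusters 1 and 5 held 915 Mock cells, 19.1% of the library (18 to 20.2), and 13 PTENα cells, 0.351% (0.187 to 0.60). The T cluster that both libraries filled, cluster 3, held 193 Mock cells, 4.02% (3.48 to 4.62), and 182 PTENα cells, 4.92% (4.25 to 5.67). B, plasma and Lef1-high T cells together were 74.7% of Mock (73.4 to 75.9) and 1.78% of PTENα (1.38 to 2.26). Any sort or enrichment that could set these shares is not given in the sources used here.

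The libraries also differed in sex-linked transcripts. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), the RNA made from the inactive X chromosome of female cells, stood at 530 CPM in Mock (518 to 543) and 5.78 CPM in PTENα (4.50 to 7.32). The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together stood at 54.4 CPM (50.5 to 58.4) and 152 CPM (145 to 159). Within Mock, B cells had 921 CPM of Xist (897 to 947) and 8.63 CPM of the Y-linked genes (6.41 to 11.4), and Lef1-high T cells had 494 and 12.6 CPM. Mock neutrophils had 44.0 CPM of Xist and 195 CPM of the Y-linked genes, and Mock monocytes or macrophages had 64.0 and 130 CPM. T cells of cluster 3 lay between, at 299 and 113 CPM in Mock, as did Mock NK cells, at 193 and 100 CPM. In PTENα the B cells had 641 CPM of Xist and 96.2 CPM of the Y-linked genes, and NK cells and cluster 3 T cells had 0 Xist UMIs, which allows up to 4.22 and 6.81 CPM. The number and sex of the animals behind each library are not given in the sources used here.

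**Figure D2:**
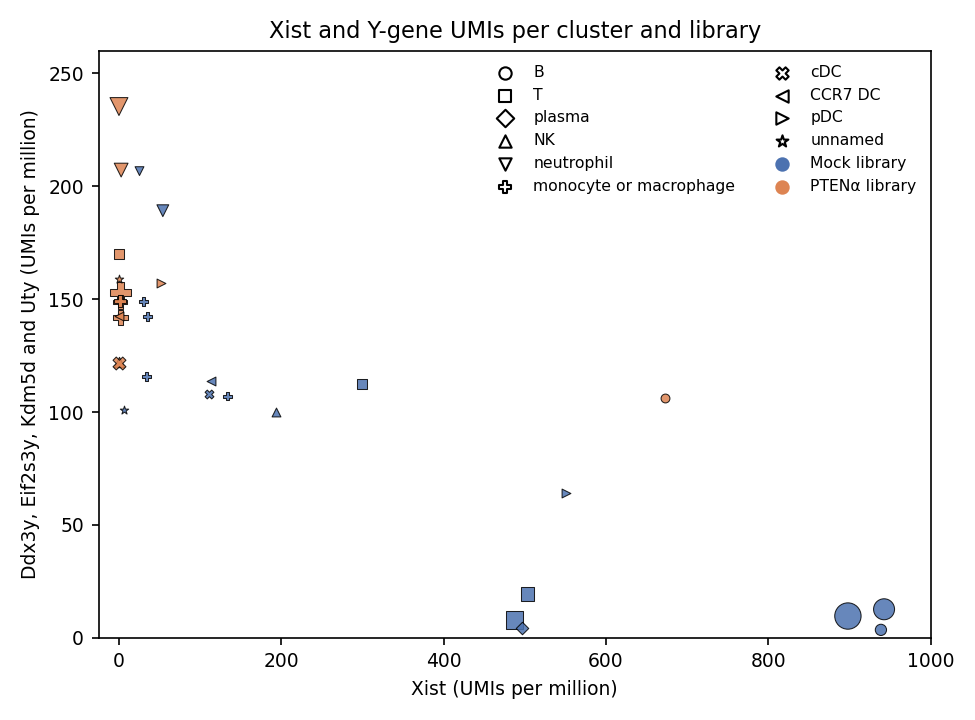
Each symbol is 1 cluster of 1 library, placed by its CPM of Xist (horizontal axis) and of the 4 Y-linked genes together (vertical axis), with shape for the class, colour for the library and size for the number of cells. The B clusters of Mock lie at high Xist, where all Mock B cells together had 921 CPM of Xist and 8.63 CPM of the Y-linked genes, while neutrophils of both libraries lie at low Xist, with 195 and 225 CPM of the Y-linked genes.

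Shares were therefore also taken in 3 smaller sets of cells, all chosen after the data were seen. Without barcodes with an Xist UMI the log2 ratios of the NK and neutrophil shares were 0.87 and 0.68, so that neither turned, and those of conventional dendritic cells and monocytes or macrophages were 2.38 and 1.81. This set still held 914 B cells (37.8%) and 460 Lef1-high T cells (19.0%) among its 2419 Mock cells, against 35 and 11 of 3670 in PTENα. Much of the lymphoid excess of Mock thus stayed in its denominator. Without B, plasma and Lef1-high T cells 1215 Mock and 3633 PTENα cells remained. Among these, monocytes or macrophages were 33.8% of Mock and 51.6% of PTENα, 1.53-fold higher (1.37 to 1.70), and conventional dendritic cells were 2.15-fold higher (1.58 to 2.97). T cells of cluster 3 were 3.17-fold lower (2.58 to 3.90), at 15.9% against 5.01%. The NK share was 8.48% against 5.42%, 1.56-fold lower (1.22 to 1.99), and the neutrophil share 33.0% against 25.9%, 1.28-fold lower (1.13 to 1.44), so that both turned direction. Among barcodes with a Y-linked UMI and no Xist UMI, 438 in Mock and 1283 in PTENα, monocytes or macrophages were again 1.53-fold higher (1.29 to 1.81) and conventional dendritic cells 2.48-fold higher (1.46 to 4.47). B cells were 21.1-fold lower there (8.25 to 68.9), T cells 3.12-fold lower (2.16 to 4.52) and neutrophils 1.46-fold lower (1.14 to 1.88), while the NK ratio was 0.780 (0.493 to 1.26). A Y-linked UMI was seen in 48.9% of Mock and 42.0% of PTENα monocytes or macrophages, at median depths of 5448 and 3482 UMIs. In neutrophils, at 1539 and 1016 UMIs, it was seen in 25.4% and 21.0%. This last set can therefore favour deeper cells and classes, and how far that moved any ratio taken in it was not tested.

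**Figure D3:**
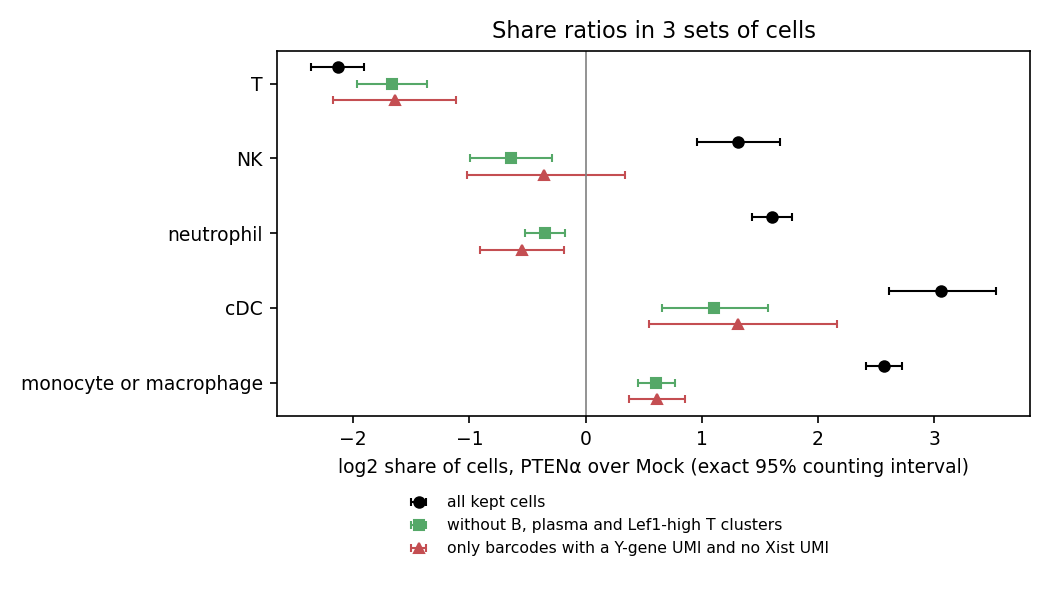
Log2 ratio of the class share, PTENα over Mock, for T cells, NK cells, neutrophils, conventional dendritic cells and monocytes or macrophages in 3 sets of cells, with exact 95% intervals of counting error. Black circles are all kept cells, green squares leave out B, plasma and Lef1-high T clusters, and red triangles are barcodes with a Y-linked UMI and no Xist UMI, and the NK and neutrophil ratios lie above 0 for all kept cells and below 0 in the other 2 sets drawn.

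Lineage genes gave the makeup of the libraries without clusters. Thinning to 1000 UMIs left out 157 Mock and 598 PTENα cells, and it kept 350 of 401 Mock and 501 of 940 PTENα neutrophils. Thinned shares therefore describe the remaining cells. After thinning, Cd79a was seen in 51.6% of Mock cells (50.2 to 53.1) and 0.709% of PTENα cells (0.445 to 1.07). The T cell receptor component Cd3e was seen in 6.77% (6.06 to 7.53) and 2.23% (1.74 to 2.81). The macrophage growth factor receptor Csf1r was seen in 2.46% (2.03 to 2.94) and 13.1% (11.9 to 14.3), and the neutrophil calprotectin subunit S100a8 in 12.8% (11.9 to 13.8) and 35.6% (33.9 to 37.3). The coreceptors Cd8a and Cd4 were seen in 2.89% (2.42 to 3.41) against 1.71% (1.28 to 2.23) and in 2.37% (1.95 to 2.85) against 0.871% (0.575 to 1.26). Foxp3, the regulatory T cell factor, was seen in 0.345% (0.197 to 0.559) and 0.129% (0.0352 to 0.330), but the log2 ratio of these shares turned from −1.42 to 0.89 when cells were thinned to 500 UMIs. The NK receptor Ncr1 was seen in 0.560% (0.366 to 0.820) and 1.26% (0.896 to 1.72), and the dendritic cell receptor Flt3 in 0.625% (0.419 to 0.896) and 1.35% (0.978 to 1.83). Flt3 summed over all cells stood at 10.8 and 10.4 CPM, so no order is read from its shares. Unthinned shares were 56.4% and 1.60% for Cd79a, 13.4% and 4.92% for Cd3e, 7.0% and 30.7% for Csf1r and 18.7% and 56.6% for S100a8. They were 6.25% and 3.03% for Cd8a, 4.71% and 2.0% for Cd4, 0.646% and 0.541% for Foxp3, 1.33% and 2.89% for Ncr1 and 2.44% and 2.81% for Flt3.

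Free RNA sets a background under these shares. In classes that should lack the gene, thinned shares were 5.14% and 0% for Cd79a in neutrophils (0 of 501 PTENα cells, which allows up to 0.599%, at median depths of 1539 and 1016 UMIs), and 3.91% and 15.3% for S100a8, 0.0909% and 0.546% for Csf1r and 0.182% and 0.546% for Flt3 in T cells (median depths 2374 and 1787 UMIs). In monocytes or macrophages (median depths 5448 and 3482 UMIs) they were 0.985% and 0.546% for Cd3e, 0.739% and 0.874% for Cd8a, 1.23% and 0.0546% for Cd4, 0% and 0% for Foxp3 and 0% and 0.109% for Ncr1, where 0 allows up to 0.739% in Mock and 0.164% in PTENα. Summed over neutrophils, Cd79a stood at 129 CPM in Mock and 1.97 CPM in PTENα.

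Summed over all cells, most of the named genes toward Mock were B cell genes, although the gene with the largest ratio was Dapl1. Cd79a (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197) stood at 1114 CPM in Mock and 14.2 CPM in PTENα, 78.6-fold lower (67.6 to 92.0). Ms4a1 (ENSMUSG00000024673, chromosome 19, 11249675 to 11266241), which encodes CD20, was 116-fold lower (85.5 to 161) and Fcmr 185-fold lower (118 to 308). Cd79b, Cd19, Pax5, Ebf1, Vpreb3 and Eaf2 were lower by 70.8-fold to 122-fold, and Dapl1 (ENSMUSG00000026989, chromosome 2, 59484653 to 59505020), a gene of naive T cells, had 3 UMIs in PTENα, a 245-fold lower level (83.5 to 1190). Toward PTENα the largest ratio of a named gene was that of Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), a ubiquitin-like protein induced by interferon, which was 7.17-fold higher (6.36 to 8.11), at 23.1 against 166 CPM. The eosinophil chemoattractant Ccl24 (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049) was 6.95-fold higher (6.47 to 7.46) and the chemokine Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383) 4.92-fold higher (4.72 to 5.13). The lectins Mgl2 and Mrc1 were 6.74-fold and 4.62-fold higher, the complement gene C1qb 4.73-fold, the growth factor Nrg1 5.62-fold, and the granzymes Gzmg, Gzmf and Gzmd 6.24-fold, 4.96-fold and 4.62-fold. Near-identical granzyme copies make the split of UMIs among Gzmd, Gzmf and Gzmg uncertain, and Gzmg had 28.7% of its PTENα UMIs in 1 cell. Among barcodes with a Y-linked UMI and no Xist UMI the log2 ratio of Gzmg over all cells turned to −0.70, that of Gzmd was 0.034, and that of Isg15 was 1.58.

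Over all cells the complement and scavenging macrophage list had a median log2 ratio of 1.80, with 27 of 27 measured members at least 1.5-fold higher, and percentile 100 among random lists. Inflammatory cytokines and chemokines (1.26, 30 higher, 1 lower, 2 between, percentile 100) were higher, with Ccl6 at 948 against 3466 CPM. The immunosuppressive myeloid list had a median of 1.11, with 18 higher, 1 lower and 6 between and percentile 100, and the arginine-degrading enzyme Arg1 stood at 329 against 1115 CPM, 3.39-fold higher (3.28 to 3.51). Glycolysis (1.09, 16 higher and 1 between, percentile 99.96) included the lactate exporter Slc16a3, 2.88-fold higher, and hypoxia (0.93, 14 higher and 8 between, percentile 100) included the angiogenic factor Vegfa, 3.06-fold higher. Interferon-stimulated genes (0.73, 18 higher and 15 between, percentile 100) included Ifitm3, 3.47-fold higher. Cytotoxic effectors (0.82, percentile 99.9), NK receptors (0.68, percentile 99.97), apoptosis and p53 (0.56, percentile 99.2) and inhibitory receptors (0.41, percentile 99.2) were above the middle 95% of random lists. Naive and memory T genes (−2.33, 15 of 17 lower, percentile 0) were lower, with the lymph node exit receptor S1pr1 at 112 against 5.11 CPM and the transcription factor Bach2 at 95.8 against 6.87 CPM. Cell cycle genes (−1.35, 37 lower and 3 between, percentile 0), with Mki67 3.48-fold lower, and MHC class II genes (−1.04, 3 higher, 9 lower and 2 between, percentile 0), with H2-Ob 25.3-fold lower, were lower, as were MHC class I genes (−0.34, percentile 1.83). The other 7 lists lay between percentiles 19.8 and 96.3. These were T cell activation and costimulation (0.19), Treg effector (0.32), interferon-gamma response (0.058), chemokine receptors and trafficking (0.22), oxidative phosphorylation (0.11), PI3K-AKT and PTEN pathway (0.032) and stress and immediate-early (0.23). Scaling by median of ratios shifted every log2 ratio by 0.11 over all cells. Values summed over all cells also follow the class shares. Within monocytes or macrophages Arg1 stood at 1764 against 1628 CPM. Medians there were 0.058 for immunosuppressive myeloid genes, −0.051 for interferon-stimulated genes and −0.20 for hypoxia. The complement and scavenging median was 0.19 in the same class, and the hypoxia median was 0.36 in NK cells.

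Within monocytes or macrophages (411 Mock and 1876 PTENα cells) 8 named genes were lower in PTENα and 8 were higher. The lower genes were the transcription factors Egr1, Fos, Atf3 and Id3, the cytokines Tnf and Osm, the chemokine Ccl4 and the regulator Phlda1. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) stood at 622 CPM in Mock and 218 CPM in PTENα, 2.85-fold lower (2.66 to 3.06). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) was 2.02-fold lower (1.93 to 2.11), Tnf 1.95-fold lower (1.75 to 2.17), at 230 against 118 CPM, Osm 1.69-fold lower (1.60 to 1.79) and Ccl4 1.60-fold lower (1.54 to 1.66). Phlda1 (1.84-fold), Atf3 (1.71-fold) and Id3 (1.95-fold) were lower too, although the log2 ratio of Id3 was 0.092 in cluster 10 alone. Isg15 was 3.31-fold higher (2.75 to 4.02), at 49.7 against 165 CPM, and the splicing regulator Ptbp1 3.03-fold higher (2.30 to 4.05). The ubiquitin-conjugating enzyme gene Ube2s was 2.33-fold higher (1.98 to 2.75), and Ccl24, which helps define cluster 9, was 1.87-fold higher (1.74 to 2.01), at 367 against 685 CPM. Arl6ip5, Plekho1, Cmtm7 and Snrpd3 were higher by 1.87-fold to 2.12-fold. Clusters 9, 10, 11 and 12 held 23.8%, 38.2%, 20% and 18% of the Mock cells of the class and 22.3%, 42.5%, 20.2% and 15% of the PTENα cells.

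Among the fixed lists in monocytes or macrophages, the stress and immediate-early list was lower (median log2 −0.16, 1 higher, 6 lower and 20 between, percentile 0), with Ier2 1.61-fold lower. Inflammatory cytokines and chemokines were lower at the median (−0.22, percentile 0), yet their members went both ways, with 5 higher, 5 lower and 21 between. Il23a, a subunit of interleukin 23, was 2.66-fold lower and Ptgs2, the prostaglandin synthase, 1.40-fold lower. Hypoxia genes were lower (−0.20, 2 lower and 19 between, percentile 0.02), with the oxygen sensor Egln3 1.44-fold lower, although this median was 0.14 in cluster 10 alone. The complement and scavenging macrophage list was higher (0.19, 3 higher and 23 between, percentile 99.99), with Pf4 1.36-fold higher (1.30 to 1.42) and C1qb 1.40-fold higher. Cell cycle genes were higher (0.20, 8 higher, 1 lower and 20 between, percentile 99.1), but the median was −0.20 when each library was clustered alone and −0.027 in cluster 10 alone. Cytotoxic effectors (0.33, percentile 100, but −1.24 with each library clustered alone) and naive and memory T genes (−1.42, percentile 0, and −0.62 with cells thinned to 1000 UMIs) stood outside the random range as well, and 14 and 8 of their members were more than 5 times higher in another class, which leaves free RNA open as their source. The other 14 lists lay between percentiles 6.63 and 84.1, among them immunosuppressive myeloid genes (0.058), interferon-stimulated genes (−0.051), interferon-gamma response (−0.061), MHC class I (−0.066) and MHC class II (−0.023). Nos2, an enzyme of nitric oxide synthesis, was 1.67-fold lower and the T cell attractant Cxcl9 3.12-fold lower within these lists. The PI3K-AKT and PTEN pathway had a median of −0.10 at percentile 6.63, with 3 of 27 members lower, and the insulin signalling adaptor Irs2 was 1.36-fold lower.

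In neutrophils (401 Mock and 940 PTENα cells) 8 named genes were lower in PTENα and 8 were higher. The heat shock chaperone Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156), which shares near-identical sequence with Hspa1b, stood at 669 CPM in Mock and 238 CPM in PTENα, 2.82-fold lower (2.40 to 3.30). The transcription factors Jun (2.07-fold, 1.89 to 2.27), Fos (1.99-fold, 1.79 to 2.21) and Egr1 (1.70-fold, 1.56 to 1.87) were lower, as were the RNA-binding regulator Zfp36, the phosphatase Dusp1, the phosphatase subunit Ppp1r15a and the cytokine Osm, by 1.73-fold to 2.20-fold. Isg15 was 3.16-fold higher (2.53 to 3.99), at 138 against 436 CPM. The hypoxia gene Ndrg1 was 3.81-fold higher (2.10 to 7.49), the cathepsin inhibitor Stfa2 2.61-fold, the acute phase gene Saa3 2.23-fold, S100a13 2.86-fold, Hsbp1 2.68-fold, Rab43 2.86-fold and N4bp1 2.07-fold. With at least 500 genes per barcode the log2 ratios of Saa3 and Stfa2 were 0.37 and 0.36.

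In neutrophils the stress and immediate-early list had the median log2 ratio −0.50, with 1 higher, 9 lower and 16 between, at percentile 0. The complement and scavenging list was higher (0.40, 6 higher, 1 lower and 9 between, percentile 99.9), with the lysosomal protease Ctsd and the matrix protein Spp1 1.31-fold and 1.32-fold higher, while Hmox1, the heme-degrading enzyme, was 1.75-fold lower. The macrophage marker Lyz2 stood at 935 against 1682 CPM in the same neutrophils. Oxidative phosphorylation genes were higher (0.25, 6 higher and 23 between, percentile 98.4), with Uqcrb 2.44-fold and Cox4i1 1.28-fold higher. Glycolysis genes stood at −0.081 (1 lower and 15 between, percentile 2.33), a sign that turned to 0.10 with at least 500 genes per barcode, and Pfkfb3 was 1.54-fold lower. MHC class II genes (−1.33, 1 higher, 5 lower and 3 between, percentile 0) and naive and memory T genes (−0.80, percentile 0) were lower. In the first of these 5 members, Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ctss, were more than 5 times higher in another class, and the median was −0.29 without barcodes with an Xist UMI and −0.55 with cells thinned to 1000 UMIs. The B cell gene Cd79a stood at 129 against 1.97 CPM in these neutrophils. Cytotoxic effectors had a median of 1.70 at percentile 100, which was −0.050 over members with at least 50 UMIs and 0.075 with cells thinned to 1000 UMIs. NK receptors had 4 measured members and no median. The other 13 lists lay between percentiles 2.82 and 87.5, with inflammatory cytokines and chemokines at 0.028 and interferon-stimulated genes at 0.18. Within them Ccl3 and Cxcl2 were 1.51-fold and 1.33-fold lower, and the interferon genes went both ways, with Ifi204 1.61-fold higher (1.18 to 2.22) and Ifit1 1.76-fold lower.

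In NK cells (103 Mock and 197 PTENα cells) 8 named genes were higher in PTENα, among them 3 granzymes, and 8 were lower. Gzmd (ENSMUSG00000059256, chromosome 14, 56129556 to 56132608) stood at 1849 CPM in Mock and 4038 CPM in PTENα, 2.18-fold higher (2.02 to 2.37). Gzmf (ENSMUSG00000015441, chromosome 14, 56205263 to 56211417) was 2.22-fold higher (2.04 to 2.43) and Gzmg (ENSMUSG00000040284, chromosome 14, 56156582 to 56159579) 2.79-fold higher (2.44 to 3.2), with 33.6% of its PTENα UMIs in 1 cell. These are proteases of cytotoxic granules with near-identical copies, so their separate levels are uncertain, and they are defining genes of cluster 8. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin, was 2.04-fold higher (1.87 to 2.22), Ube2s 2.64-fold (1.90 to 3.75) and Khdc1a 2.68-fold (1.83 to 4.03). The T cell and NK chemokine Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) was 3.03-fold lower (2.80 to 3.28), at 4080 against 1348 CPM, and Xcl1, which attracts dendritic cells, was 3.17-fold lower (2.68 to 3.77). The quiescence factor Klf2 was 3.68-fold lower (2.72 to 5.02), the interleukin 7 receptor Il7r 5.53-fold (3.27 to 9.80), the activation and tissue retention gene Cd69 4.11-fold (2.71 to 6.37) and Cd7 3.13-fold (2.16 to 4.59). For 4 other named genes 1 cell held most of the UMIs of the higher library, which was 98.6% for Cma1, 72.8% for Gadd45g, 70.5% for Ifng and 61.3% for Cxcl10. Cma1 and Gadd45g were higher in PTENα, and Ifng and Cxcl10 were lower. T cells also carry Il7r, Cd7, Klf2 and Ccl5, and whether the 101 cells of this class that calls per cell put with T cells bear on these ratios was not tested.

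In NK cells with a Y-linked UMI and no Xist UMI, 28 in Mock and 64 in PTENα, the log2 ratios of Gzmf, Gzmg and Ifng turned to −0.015, −1.14 and 1.90, and those of Gzmd, Klf2 and Cd7 were 0.12, −0.25 and −0.14. In the same cells the ratios of Spp1 (2.54, 2.19 to 2.95), Khdc1a (2.97, 1.54 to 6.28) and Ube2s (2.04, 1.19 to 3.66) and those of Ccl5 (0.471, 0.385 to 0.575), Xcl1 (0.510, 0.349 to 0.742) and Cd69 (0.324, 0.151 to 0.667) kept their direction with intervals that excluded 1. Without the cell of each library with most UMIs of the gene the intervals of the first 5 still did, while that of Cd69 (0.463, 0.159 to 1.30) included 1. The ratio of Gzmf there was 0.989 with every cell and 4.38 (3.38 to 5.76) without the cell of each library with most Gzmf UMIs. With at least 500 genes per barcode the log2 ratio of Il7r was −0.39 in place of −2.47. None of the 29 Mock NK cells with an Xist UMI and no Y-linked UMI had a UMI of Gzmd, Gzmf, Gzmg or Spp1, which allows a share of cells with a UMI of up to 10.3%. With every NK cell thinned to 1000 UMIs, Gzmd was seen in 11.7% of Mock and 33.7% of PTENα NK cells and Spp1 in 18.4% and 44.9%. Ccl5 was seen in 64.1% and 36.4% and Klf2 in 37.9% and 10.7%. Unthinned, these shares were 14.6% and 36.5% for Gzmd, 31.1% and 63.5% for Spp1, 75.7% and 50.3% for Ccl5 and 52.4% and 21.8% for Klf2, at median depths of 2862 and 2956 UMIs.

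Among the lists in NK cells, glycolysis was higher (median log2 0.42, 3 higher and 11 between, percentile 100), with Pgk1 1.63-fold higher (1.33 to 2.01) and Gapdh 1.35-fold higher (1.24 to 1.48). Hypoxia genes (0.36, 2 higher, 1 lower and 10 between, percentile 99.9), with Ddit4 2.08-fold higher (1.29 to 3.46), and immunosuppressive myeloid genes (0.26, 3 higher, 1 lower and 12 between, percentile 99.5) were higher too. Myeloid markers moved the same way in NK cells, with Lyz2 at 83.4 against 263 CPM and S100a8 at 23.8 against 91.3 CPM. Stress and immediate-early genes were lower (−0.38, 5 lower and 18 between, percentile 0), and their median was −0.046 among cells with a Y-linked UMI and no Xist UMI. Naive and memory T genes were lower (−0.82, 1 higher, 8 lower and 4 between, percentile 0), with the homing receptor Sell at 250 against 142 CPM. NK receptors and their regulators were lower (−0.23, 6 lower and 16 between, percentile 1.29), with the transcription factor Eomes at a ratio of 0.572 (0.399 to 0.819) and Klrc2 at 0.509. This median turned to 0.11 with each library clustered alone and to 0.12 among cells with a Y-linked UMI and no Xist UMI. MHC class I genes (−0.22, 4 lower and 11 between, percentile 1.83) and MHC class II genes (−0.49, 3 lower and 4 between, percentile 1.18) were lower, and the B cell gene Cd79a moved the same way, with 22 UMIs (52.4 CPM) in Mock NK cells and 0 UMIs in PTENα. The cytotoxic effector list had members on both sides, 4 higher, 5 lower and 10 between, with a median of 0.0081 at percentile 58.3. The other 12 lists lay between percentiles 3.04 and 90.4, with inhibitory receptors at −0.19, where Ctla4 was 1.81-fold higher (1.26 to 2.68) and Cd160 stood at 133 against 45.0 CPM.

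T cells as a whole (1108 Mock and 195 PTENα cells) compare mostly Lef1-high cells of Mock with cluster 3 cells of PTENα, since clusters 1 and 5 held 915 of the Mock cells and cluster 3 held 182 of the PTENα cells. Naive T cell genes were lower in PTENα and effector genes higher. Dapl1 had 1 UMI in PTENα, a 131-fold lower level (23.4 to 5163), and the naive T factor Tcf7 was 12.8-fold lower (6.93 to 26.8). Igfbp4, Dusp10 and Ripor2 were lower by 10.0-fold to 11.5-fold, and Rflnb, with 2 UMIs in PTENα, was 18.6-fold lower (5.08 to 154). Cmah and Nsg2 had 0 UMIs in PTENα, with log2 ratios of −3.53 and −3.38 at the floor of 3 counts. Their intervals allowed ratios of up to 0.107 and 0.119. The inhibitory receptor gene Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553) was 10.8-fold higher (7.88 to 14.9), Gzmf 21.9-fold (18.3 to 26.2), the lipid droplet gene Hilpda 8.0-fold, the metallothionein Mt1 12.2-fold and the leukotriene receptor Ltb4r1 10.7-fold. Apoe was 18.3-fold higher (12.8 to 26.6), Ptgs2 11.2-fold (8.17 to 15.4) and Hmox1 70.7-fold (30.9 to 199), with 30.7%, 42.4% and 72.9% of their PTENα UMIs in 1 cell, and the log2 ratio of Apoe was 0.88 without doublet removal in place of 4.20. In cluster 3 alone the log2 ratio of Dapl1 was 0.018 and that of Igfbp4 turned to 2.76. Pdcd1, Il17a, Trdc and Ctla4 are defining genes of cluster 3, so their levels in T cells and its size are not independent. Scaling by median of ratios shifted every T cell log2 ratio by −0.29.

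Over all T cells 13 lists stood above the middle 95% of random lists. Among them were inflammatory cytokines and chemokines (3.22, 18 of 18 higher), immunosuppressive myeloid (2.40, and 1.48 with cells thinned to 1000 UMIs), complement and scavenging (2.22), cell cycle (1.71, 34 higher and 2 between), cytotoxic effectors (1.66, 20 higher, 1 lower and 1 between) and glycolysis (1.61). The remainder of the 13 were NK receptors (1.39), hypoxia (1.38), Treg effectors (1.31), inhibitory receptors (1.28), MHC class II (1.07), T cell activation and costimulation (0.84) and interferon-stimulated genes (0.67). Naive and memory T genes stood at −2.27 with 14 of 17 lower, at percentile 0. The other 7 lists lay between percentiles 28.6 and 97.2, with interferon-gamma response at 0.46, chemokine receptors at 0.64 and apoptosis and p53 at 0.63. Cell cycle genes took 0.228% of T cell UMIs in Mock (0.222 to 0.233) and 0.611% in PTENα (0.589 to 0.634), a log2 ratio of 1.42 that was 0.21 without the Lef1-high clusters. That share was 0.354% in both libraries in NK cells, 0.143% (0.138 to 0.148) and 0.151% (0.148 to 0.154) in monocytes or macrophages, 0.125% and 0.117% in neutrophils and 0.261% and 0.406% in conventional dendritic cells.

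In the T cluster that both libraries filled (cluster 3, 193 Mock and 182 PTENα cells, median depths 2564 and 1800 UMIs), which was set apart after the data were seen, Pdcd1 was 2.48-fold higher in PTENα (1.81 to 3.44), at 104 against 259 CPM, and Havcr2, which encodes the inhibitory receptor TIM-3, was 3.15-fold higher (1.55 to 6.80), while the inhibitory receptor gene Ctla4 was 1.25-fold lower (1.01 to 1.55). Gzmb was 1.19-fold lower (1.04 to 1.37). Trdc, the constant part of the δ chain of γδ T cell receptors, was 2.17-fold higher (1.68 to 2.81), Il17a 1.62-fold higher (1.34 to 1.96) and Gzmf 5.09-fold higher (4.25 to 6.13). Foxp3 was 1.99-fold lower (1.10 to 3.78), at 72.3 against 36.3 CPM. Izumo1r, a folate receptor family gene of regulatory T cells, was 5.04-fold lower (2.58 to 11), the chemokine Ccl1, with 2 UMIs in PTENα, 23.3-fold lower (6.19 to 197), and the chromatin organiser Satb1 2.21-fold lower. Intervals of the ratio included 1 for Cd3e (343 and 315 CPM), Cd8a (234 and 197 CPM), Cd4 (111 and 90.8 CPM), Lag3 (28.6 and 27.2 CPM), Tox (79.0 and 61.3 CPM), Ifng (70.6 and 70.3 CPM) and Mki67 (170 and 145 CPM). Apoe was 24.3-fold higher (11.5 to 61.7), Hmox1 46.6-fold (12.4 to 392, with 2 UMIs in Mock) and Ptgs2 3.12-fold (2.23 to 4.43), and markers of myeloid cells moved the same way, with Lyz2 at 544 against 1185 CPM and S100a8 at 30.2 against 340 CPM. The heat shock genes Hspa1a and Hspa1b (3.59-fold and 3.88-fold), Mt1 (3.70-fold) and Dgat1 (2.87-fold) were higher, and Rgs10 (2.74-fold), Heca (3.13-fold), Akna (2.48-fold), Arid4a (2.54-fold) and Ms4a4b (1.74-fold) were lower. Of the Mock cells of this cluster 24.4% had an Xist UMI, against 0% of the PTENα cells. Among its cells with a Y-linked UMI and no Xist UMI the log2 ratio of Izumo1r was −1.12 in place of −2.33. That of Gzmf was 2.85 in place of 2.35. Values of Pdcd1, Havcr2 and Foxp3 in those cells are not given here, so the bearing of the Xist difference on them stays open.

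In this cluster cytotoxic effectors were higher (median log2 0.41, 9 higher, 2 lower and 10 between, percentile 99.99), as were hypoxia (0.32, 7 higher and 10 between, percentile 99.2), glycolysis (0.34, 5 higher and 10 between, percentile 99.9) and apoptosis and p53 (0.31, percentile 99.5). Among the cytotoxic effectors Gzmb was lower. Gzmd and Gzmf were higher in monocytes or macrophages and neutrophils too, which leaves free RNA open as part of their source. Lists of myeloid genes were higher beside the Lyz2 and S100a8 levels just given, with inflammatory cytokines and chemokines at 1.48 (16 of 18 higher), MHC class II at 1.08, immunosuppressive myeloid at 0.78 and complement and scavenging at 0.66. Naive and memory T genes (−0.59, 7 lower and 6 between, percentile 0), interferon-stimulated genes (−0.32, 4 higher, 7 lower and 12 between, percentile 0.35) and MHC class I genes (−0.20, percentile 2.33) were lower. Inhibitory receptors (−0.0029, 5 higher, 2 lower and 7 between), Treg effectors (−0.057), NK receptors (−0.014), T cell activation (0.052), cell cycle (0.080) and stress genes (0.016) were within the random range.

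**Figure D4:**
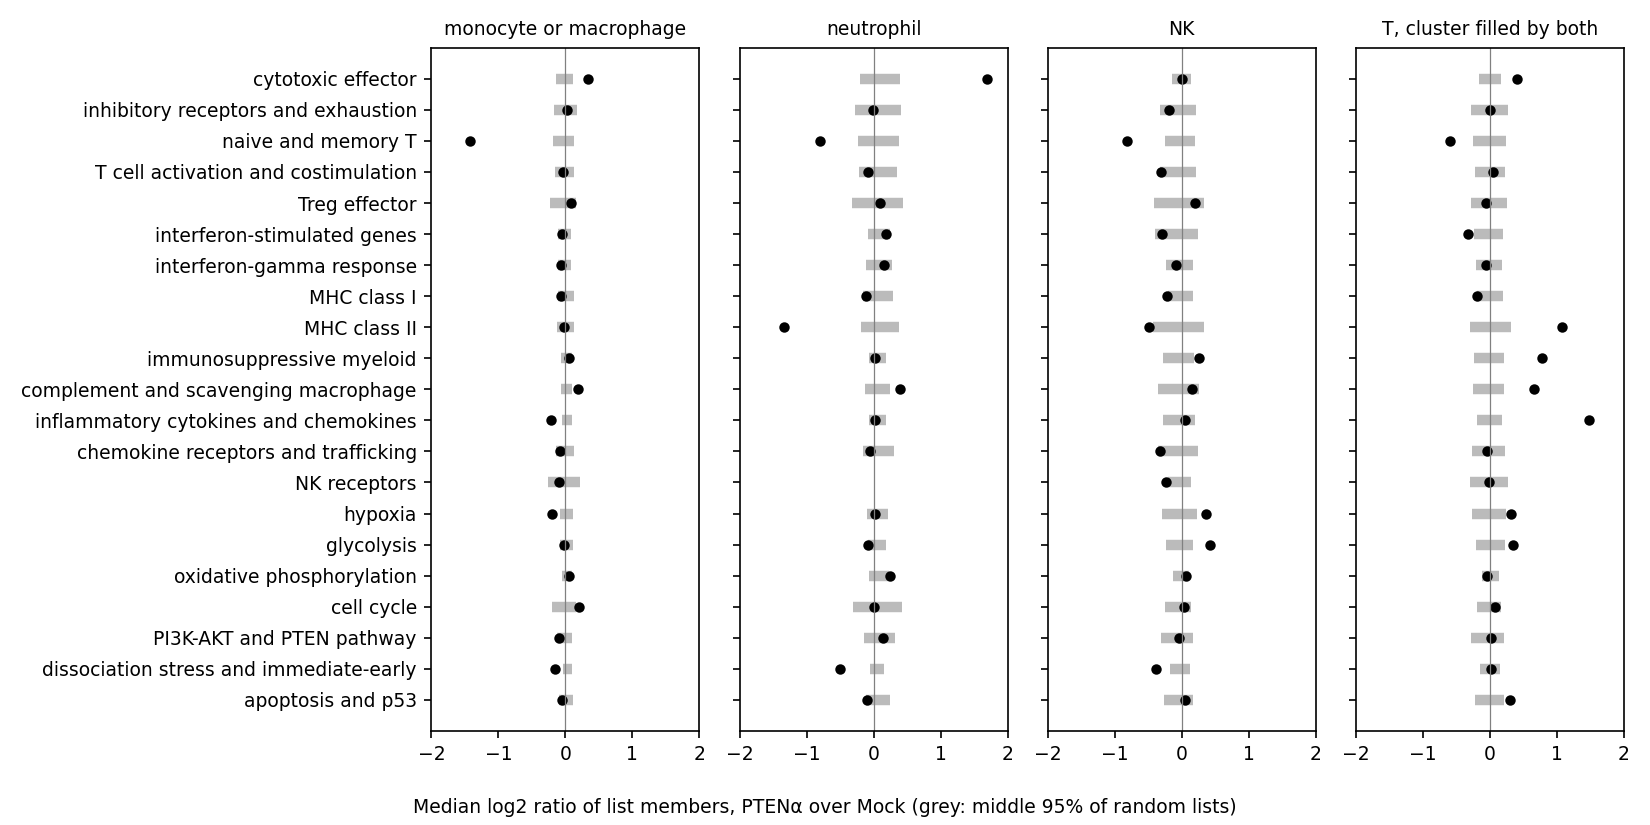
Median log2 ratio, PTENα over Mock, of each of the 21 fixed gene lists (dots) in monocytes or macrophages, neutrophils, NK cells and the T cluster that both libraries filled, with grey bars for the middle 95% of 10000 random lists of the same size and expression. The stress and immediate-early list lies below the grey bar in the first 3 panels (−0.16, −0.50 and −0.38) and inside it in the T cluster (0.016).

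T cells were reclustered to name subsets. CD8 T cells made up 41.2% of Mock T cells (456 cells, 38.2 to 44.1) and 52.3% of PTENα T cells (102 cells, 45.1 to 59.5), but 77.4% (73.8 to 80.7) and 55.7% (48.2 to 63.1) of the T cells in named subsets. The log2 ratio of the CD8 share of T cells, 0.35, turned to −1.46 and −0.070 at Leiden resolutions 0.5 and 2, and to −0.53 and −0.19 with gates on unthinned and thinned UMIs, so no direction is read from it. Regulatory T cells made up 7.22% (80 cells, 5.77 to 8.91) and 8.21% (16 cells, 4.76 to 13). The log2 ratio of this share, 0.18, was 2.38 and 2.14 at Leiden resolutions 0.5 and 2. It turned to −1.31 within cluster 3, so neither size nor direction is read from it. T cells with γδ receptor genes made up 4.78% (3.60 to 6.21) and 33.3% (26.8 to 40.4), and 46.8% and 6.15% stayed unnamed. No recluster was named CD4 T. The ratio of CD8 to regulatory T cells was 5.70 in Mock (4.49 to 7.32) and 6.38 in PTENα (3.74 to 11.6), intervals that overlap. Its log2 ratio, 0.16, turned to −3.84, −2.21, −1.45 and −0.78 under the same settings. A recluster of 2 Mock and 7 PTENα cells passed the markers of regulatory T cells but was left unnamed because Lyz2 was among its leading genes, a rule set after the clusters were seen. With it regulatory T cells numbered 82 and 23, and the log2 ratios of their share and of CD8 to regulatory T cells were 0.67 and −0.33. Gates gave γδ T shares of 3.18% and 20.8% after thinning and 3.97% and 25.1% before it. Within cluster 3 alone CD8 T cells made up 47.7% (40.4 to 55) and 51.1% (43.6 to 58.6), γδ T cells 27.5% (21.3 to 34.3) and 35.7% (28.8 to 43.1), and regulatory T cells 21.8% (16.2 to 28.3) and 8.79% (5.11 to 13.9). The log2 ratio of the γδ share was 2.80 over all T cells, 3.59 at Leiden resolution 2 and 0.38 within cluster 3, and that of the regulatory T share was 0.18 and −1.31.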

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

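The alternatives behind the B share were planned before the data were examined, and the tests of explanations in this part were chosen after the results they bear on were seen. Some gene lists had medians of opposite sign in different classes, and the differences between classes were not tested. The MHC class II list stood at −1.33 (median log2 ratio, PTENα over Mock) in neutrophils and 1.07 in T cells, the NK receptor list at −0.23 in NK cells and 1.39 in T cells, and the glycolysis list at −0.081 in neutrophils and 0.42 in NK cells. In NK cells the NK receptor median turned to 0.11 with each library clustered alone and to 0.12 among barcodes with a Y-linked UMI and no Xist UMI. Neutrophil glycolysis turned to 0.10 with at least 500 genes, 0.0022 over members with any UMI and 0.017 among the same barcodes. The hypoxia list stood at −0.20 in monocytes or macrophages and 1.38 in T cells, and the list of inflammatory cytokines and chemokines at −0.22 and 3.22 in the same classes. In cluster 10 alone the hypoxia median of monocytes or macrophages turned to 0.14. Medians over all T cells compare mostly Lef1-high cells of Mock with cluster 3 cells of PTENα. In cluster 3 alone they were 0.32 for hypoxia, −0.014 for NK receptors, 1.08 for MHC class II and 1.48 for inflammatory cytokines and chemokines. Outside the main measurements, Xist stood at 530 CPM over all kept Mock cells, against 5.78 CPM in PTENα, and 11.6% of PTENα barcodes lay over the mitochondrial limit, against 3.70% of Mock barcodes.

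B, plasma and Lef1-high T cells were nearly confined to the Mock library, and they carried Xist in both libraries, at 787 CPM in Mock and 524 CPM in PTENα, with an Xist UMI in 61.4% and 30.3% of these cells. Their Y-linked CPM in Mock was 7.35% of that in all other Mock cells, which is what cells of female animals in the Mock library would give, whereas in PTENα the same classes had more, a Mock to PTENα ratio of 0.0963 (0.0482 to 0.218) that rests on 9 Y-linked UMIs in PTENα. That ratio argues against fewer such cells in PTENα tumours as the whole cause, since a smaller number of the same cells would keep their Y-linked level. A choice of filter or clustering was argued against by the B share, whose log2 ratio nearest to 0 over those alternatives was −5.18. Whether PTENα tumours also held fewer B cells stays open: among barcodes with a Y-linked UMI and no Xist UMI the log2 ratio was −4.40, but with 1 library per group this cannot be told apart from the library.

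NK cells had 16 named genes that differed between the libraries, and a single cell with most of the UMIs could account for 25% of them, which argues against it as the whole cause. For the 12 others, the median log2 ratio of the share of cells with a UMI, taken toward the direction in all NK cells, was 1.28 in all NK cells and 0.60 in those with a Y-linked UMI and no Xist UMI. All 12 pointed the same way there, but none of these 12 intervals excluded 1 with 28 Mock and 64 PTENα cells. By UMIs 6 of the 12 ratios excluded 1 in the direction of all NK cells and 1, that of Gzmg, the other way, and without the cell of each library with most UMIs of the gene these numbers were 7 and 1. These go against cells of female animals in Mock as the whole cause. However, the 12 genes were picked by their ratios in all NK cells, which include these cells, so their direction here is not independent. The Gzmf ratio also moved from 0.989 to 4.38 without that cell of each library. This is far past its counting interval, so the whole cause stays open. Within Mock, NK cells with an Xist UMI and no Y-linked UMI had more of the lower genes than those with a Y-linked UMI and no Xist UMI. Ccl5 was at 12370 against 1433 CPM, Xcl1 2008 against 403, Klf2 822 against 96.0, Cd7 776 against 76.8, Cd69 487 against 147 and Il7r 320 against 64.0. Cells with Xist thus raised the Mock levels of these genes. For the 12 genes as a set their part cannot be told apart from a difference in tumour NK cells, which stays untested.

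The stress and immediate-early list was lower in PTENα monocytes or macrophages, neutrophils and NK cells. With every cell thinned to 1000 UMIs the medians were −0.22, −0.69 and −0.34. They lay below the random lists of the same thinned cells (lower ends −0.081, −0.13 and −0.31), by a narrow margin in NK cells. The difference thus stayed when each cell had equal weight. Thinning leaves a cell's expected share of each gene unchanged, and it kept 350 of 401 Mock but 501 of 940 PTENα neutrophils. It therefore cannot decide whether the depth of the cells was the cause. Among barcodes with a Y-linked UMI and no Xist UMI the medians were −0.20 in monocytes or macrophages and −0.38 in neutrophils, below random lists of the same barcodes (lower ends −0.086 and −0.14), which argues against cells of female animals as the cause there, while the NK median was −0.046, inside its range (−0.22 to 0.21), which such cells could explain. Handling of the cell suspension before lysis cannot be told apart from the group, and the median of 0.016 in the T cluster that both libraries filled decides nothing, since classes can respond unequally. A difference between tumours of the groups stays open and untested.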

How the results depend on the processing

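No paired analysis was possible because each group is 1 library and no test was run. Alternatives with cells chosen by Xist or Y-linked UMIs, without B, plasma and Lef1-high T clusters, the main cluster alone for single genes, thinning for lists, and T subsets named by markers alone were added after the data were seen, and the others were planned. Values are log2 ratios, PTENα over Mock, or medians of them for lists. A share, ratio or gene was taken as moved where it left its counting interval. A list median was taken as moved where it changed by at least the distance from the midpoint to an end of its random range. Where a value moved by these rules or turned direction, the cause was not tested. The 103 Mock NK cells and the 16 regulatory T cells of PTENα limit what those classes can show.

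With at most 5% mitochondrial UMIs the shares were −2.51 for T, 2.04 for cDC, 2.20 for monocytes or macrophages and 1.14 for neutrophils, and with 20% cDC was 2.52. With at least 500 genes they were −5.79 for B, 1.86 for NK, 2.89 for monocytes or macrophages and 0.30 for neutrophils, the NK stress list was −0.18 and neutrophil glycolysis turned to 0.10. With each library clustered alone the shares were −1.18 for T, 0.58 for NK, 3.56 for cDC and 2.39 for monocytes or macrophages, and the NK stress list was −0.54. There the NK receptor list in NK cells turned to 0.11, and in monocytes or macrophages cell cycle turned to −0.20 and cytotoxic effectors to −1.24. Calls per cell by marker means gave −1.65 for T, 1.75 for NK, 2.57 for cDC and 2.02 for neutrophils.

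T cells at Leiden resolution 0.5 gave −1.46 for CD8, 2.38 for Treg and −3.84 for CD8 to Treg, and at resolution 2 −0.070 for CD8, 2.14 for Treg, 3.59 for γδ and −2.21 for CD8 to Treg. Gates gave −0.53 for CD8 and −1.45 for CD8 to Treg unthinned, and −0.19 and −0.78 thinned, so that under all 4 settings CD8 and CD8 to Treg turned from 0.35 and 0.16. Subsets named by markers alone gave −0.33 for CD8 to Treg. List members with at least 50 UMIs turned cytotoxic effectors in neutrophils to −0.050, members with any UMI turned neutrophil glycolysis to 0.0022, and the mean over cells gave a T cell cycle share of 1.24.

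In the main cluster alone Dapl1 (0.018) and Igfbp4 (2.76) in T cells and Id3 (0.092) in monocytes or macrophages turned, as did the T lists of NK receptors (−0.014), Treg effectors (−0.057), inhibitory receptors (−0.0029) and interferon-stimulated genes (−0.32). In monocytes or macrophages hypoxia turned to 0.14 and cell cycle to −0.027, and the stress list was −0.27. Without B, plasma and Lef1-high T clusters, T cells are that same cluster, with the same values for Dapl1 (0.018), Igfbp4 (2.76), NK receptors (−0.014), Treg effectors (−0.057), inhibitory receptors (−0.0029) and interferon-stimulated genes (−0.32). In that set the shares of NK (−0.64) and neutrophils (−0.35) turned, T was −1.67, cDC 1.10 and monocytes or macrophages 0.61. T subsets there were 0.38 for γδ, −1.31 for Treg (turned) and 1.41 for CD8 to Treg, and the T cell cycle share was 0.21.

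Without barcodes with an Xist UMI the shares were 0.87 for NK, 2.38 for cDC, 1.81 for monocytes or macrophages and 0.68 for neutrophils, the NK stress list was −0.091 and the T cell cycle share 1.34. With only barcodes with a Y-linked UMI and no Xist UMI the shares of NK (−0.36), neutrophils (−0.55) and CD8 T (−0.14) turned, and the others were −4.40 for B, −1.64 for T, 1.31 for cDC, 0.61 for monocytes or macrophages and 0.54 for γδ T. Gzmf (−0.015), Gzmg (−1.14) and Ifng (1.90) in NK cells and Gzmg over all cells (−0.70) turned there. The lists of NK receptors in NK (0.12) and T cells (−0.28), neutrophil glycolysis (0.017) and interferon-stimulated genes in T cells (−0.22) turned too. The stress list was −0.046 in NK cells and −0.38 in neutrophils, and the T cell cycle share 0.31.

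Of the values recomputed, Leiden resolutions 0.5 and 2 over all cells left all 153 unmoved, and median-of-ratios scaling moved 9 and left 158. The limit of 20% mitochondrial UMIs moved 5 and left 148, and no doublet removal moved 12 and left 141. Double removal moved 16 and left 137, and 15 principal components moved 13 and left 139. None of these turned a gene, or a share whose counting interval excluded equality, or a list that lay outside its random range. Sign changes of other values were not counted. Equal class weights moved 18 of the 20 genes named over all cells and turned none, which fits their construction, since B cells then count no more than other classes. With cells thinned to 1000 UMIs the neutrophil stress list was −0.69. Thinning the classes to 1000 UMIs moved 27 of 64 named genes, means over cells moved 29 of 84, and neither turned one. With no minimum of UMIs or CPM 12 of the 20 genes named over all cells were the same.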

Other observations

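Isg15 was higher in PTENα in each of the 4 compared sets, as was Bst2 of the same list, while the median of the other interferon-stimulated genes had no common sign. Its ratio was 3.31 in monocytes or macrophages (2.75 to 4.02), 3.16 in neutrophils (2.53 to 3.99), 3.66 in NK cells (1.41 to 12.0) and 1.92 in the T cluster that both libraries filled (1.26 to 2.96). The measured members other than Isg15, 31, 29, 12 and 22 genes in these sets, had median log2 ratios of −0.066, 0.14, −0.32 and −0.38. Among barcodes with a Y-linked UMI and no Xist UMI the Isg15 ratio was 2.98 (2.22 to 4.08), 3.60 (2.32 to 5.80), 4.01 (0.922 to 36.4) and 3.97 (1.09 to 21.7), so that only the NK interval included 1. Isg15 and Bst2 were singled out after their values were seen, and a difference between libraries that affects single transcripts was not tested.

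Across these 4 sets, 12 genes had a ratio whose bound nearest to 1 was past 1.5-fold toward PTENα in at least 3 sets, with no minimum of UMIs or CPM, and 13 had one toward Mock. The 12 were Arg1, Bst2, Ccl24, Gzmd, Gzmf, Gzmg, Lyz2, Mt1, Ptbp1, S100a8, S100a9 and Serpinb9b, which mix transcripts abundant in other cells of the PTENα library (Lyz2, S100a8, S100a9, Arg1 and granzymes) with Bst2, the antiviral tether, and Ptbp1, the splicing regulator. Several of these levels were low, such as 6.54 CPM of Gzmg in PTENα monocytes or macrophages. Bst2 had log2 ratios of 0.92, 1.97, 1.30 and 0.61 in monocytes or macrophages, neutrophils, NK cells and the T cluster, and Ptbp1 had 1.60, 1.54, 0.79 and 1.67. The 13 toward Mock were Bank1, Cd79a, Cd79b, Cmah, Ebf1, Fcmr, Fos, H2-Ob, Izumo1r, Ly6d, Ms4a1, Mzb1 and Satb1, mostly genes of B cells, which are abundant in the Mock library.

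The Mock lymphoid cells included cycling B cells. Cluster 7, led by Mef2b, Aicda and Mki67, held 233 Mock and 2 PTENα cells, and cell cycle genes took 0.515% of B cell UMIs in Mock and 0.191% in PTENα. Among Mock B cells, 6 of the 42 with a Y-linked UMI (14.3%) had an Xist UMI, against 1708 of the 2586 without one (66.0%). Among Lef1-high T cells these numbers were 2 of 22 (9.09%) and 453 of 893 (50.7%). Over all kept cells 48 Mock and 6 PTENα cells had both Xist and Y-linked UMIs.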
